A study of Mus musculus with 6 samples.

How the data were processed

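Gene expression was measured in the conjunctival epithelium of mouse embryos at embryonic day 14.5 on 6 Illumina bead arrays, 3 labelled Sox9 knockout and 3 wild type. Per the labels' protocols, embryos of a mixed FVB and 129 background were frozen and sectioned at 10 micrometres, and the epithelium was captured by laser microdissection after eosin staining. The labels do not say how a region was delimited beyond its name. Total RNA (15 ng) was amplified to 3 to 5 micrograms of cDNA with a NuGEN WT-Ovation Pico kit and labelled with biotin. The series' design text states 3 wild-type and 3 knockout embryos, with the cDNA of each region pooled before hybridisation, whereas the extraction protocol speaks of lens tissue from a single embryo. The design text was followed here. By that text the arrays of a genotype share embryos, though the sources used here do not list the embryos of each array. P-values for genotype over regions are therefore too small as a measure of variation between embryos.

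The deposited table gave, per the file headers, an average signal intensity for each probe and array, the standard error of that intensity over beads, the number of beads and a detection p-value. GenomeStudio is the tool named in the submitters' processing notes, without a version. The deposited signal intensities were not background-subtracted and had not been normalized between arrays, as their differing medians showed. The authors' detection p-value compares a probe with the negative controls of its array, and its steps corresponded to 936 controls. A second table held the authors' processed intensity values on a linear scale. Their medians were 4.24 to 4.25 and negative values were present, which shows a subtracted background. The method of normalization is not given in the sources used here, and neither is any centring. Each column of that table matched the signals of its own array, with a rank correlation of 0.983 over all probes, and the direction was the same. The table of signals also held 1315 entries without a probe identifier, of which 1210 had values, on the 3 knockout arrays alone. These were not used.

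The arrays held 45281 probes, of which 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Symbols were updated through the NCBI gene table of assembly GRCm38.p6, 34807 by Entrez identifier and 11 by accession. The file's symbol was kept for 67, and 10 symbols changed. The array's own genome build is not given in the sources used here, so no coordinates are printed.

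Signals were corrected for background with limma's normexp method, with the negative-control parameters inferred from the detection p-values and an offset of 16, then quantile-normalized and taken to log2. A probe was kept if its detection p-value was under 0.05 on at least 2 of the 6 arrays, and the brightest such probe stood for its gene, which left 11147 genes. Where a gene was not detected on any array of 1 side, its fold was given as a bound. The bright side was then set against the higher of the probe's own value and the lowest normalized value among detected probes on that array. Fold changes are on the scale of signal plus offset and understate the change of dim genes.

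A linear model with terms for region and genotype was fitted to all 6 arrays with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Contrasts were knockout minus wild type, the mean of nasal and temporal minus dorsal, and nasal minus temporal. A further fit tested whether the knockout effect in dorsal differed from the mean effect in nasal and temporal, with 1 residual degree of freedom. Within a region there was 1 array per genotype, so differences there are values without a test. The bead standard errors printed beside them cover measurement on the array only. An exact permutation test of 3 arrays against 3 cannot give a p-value under 0.1, so none was used. The number of arrays limits the precision of every comparison.

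In all, 29 gene lists were fixed before the data were examined and 28 were tested. They covered heparan sulfate synthesis and core proteins, chondroitin sulfate and hyaluronan, cartilage, basement membrane, ocular gland, FGF and ERK response, Wnt, BMP, Notch and Hedgehog pathways, keratins and adhesion, cornea and conjunctiva, epidermis, placode, cell cycle, p53 response, immediate early genes and hypoxia. The others marked periocular mesenchyme, lens, retina, pigment cells, muscle, erythroid cells, endothelium, macrophages and nerve. The list of X inactivation and Y-linked genes was used only to describe the arrays. Lists with at least 3 detected members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 28 lists. Alternatives used an estimated correlation or fry, which tests whether a list's genes move, on balance, one way and compares no list with other genes. The list test on nasal minus temporal was added after seeing the data.

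Genes named in the text followed a rule fixed with the lists. Among genes past the threshold, the 12 largest changes in each direction with the same sign in all 3 regions were to be named for the knockout, and 6 per direction for the other contrasts. Where too few passed, the lowest p-values among genes with an absolute log2 difference of at least 1 and the same sign filled the places. Within each region the 4 largest differences per direction among genes detected on both arrays were named. Of each list, 2 to 4 members were to be named, those past the threshold first and then by p-value. Predicted genes, clone names and sex-linked genes were left out. Other genes were chosen after their values were seen.

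The fits were tested on simulated data with 50 genes changed at each of 4 sizes. For the knockout contrast over 11147 genes, 4 of 50 genes with a true absolute log2 change of 1 were called, 49 of 50 at 2, 49 at 3 and 50 at 4, with 9 unchanged genes called. The interaction called 0, 2, 11 and 37 of 50. The adjustment is easier to pass when many genes change, so these rates need not hold where few do. Noise was drawn independently for each gene, from variances that limma had already drawn towards a common value. Real variances differ more, so these rates can be too high. A 35-gene list shifted by 1 log2 unit was called by camera at the preset correlation and missed with the estimated correlation (adjusted p = 0.107). Alternatives covered the background correction, its offset, median scaling, the authors' values (negative ones set to 0, with 16 added before log2), the detection filter, the mean of a gene's probes, the covariates, array weights, a variance trend, other thresholds, and each array or region pair left out in turn. The other Sox9 probe was added as an alternative after seeing the data. All arrays were on a single chip, so chip was no batch. By the file headers the arrays labelled knockout held positions A, B and C and wild type D, E and F. Position on the chip therefore cannot be told apart from genotype. Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.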

Results

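The series profiled the conjunctival epithelium, the surface layer that lines the eyelids and covers the white of the eye, from its nasal, temporal and dorsal parts at embryonic day 14.5. The nasal and temporal parts give rise to the Harderian and lacrimal glands. Mice labelled knockout carried floxed Sox9 alleles and the Le-Cre driver, which acts in the surface ectoderm of the eye, and Sox9 encodes a transcription factor of gland buds and cartilage. There was 1 array for each genotype and region, 3 arrays per genotype in all. Detected probes numbered 18040 (39.8%) on the knockout nasal array, 18877 (41.7%) on the knockout temporal, 20333 (44.9%) on the knockout dorsal, 19654 (43.4%) on the wild-type nasal, 19969 (44.1%) on the wild-type temporal and 20660 (45.6%) on the wild-type dorsal array. Median signals lay between 77.3 and 83.7 intensity units, and the median probe was read from 43 beads on each array.

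Sox9 itself was not lower on the arrays labelled knockout as a group. The brighter of its probes (ILMN_2778151) averaged 10.04 ± 0.18 on a log2 scale in the arrays labelled knockout and 9.55 ± 1.10 in wild type. The SD is over the 3 regions (n = 3 arrays each), not over embryos. In nasal epithelium Sox9 was 3.79-fold higher on the array labelled knockout (10.21 against 8.29, log2 difference 1.92, bead SE 0.08). The temporal arrays were 0.05 apart (10.06 against 10.01, bead SE 0.05), and in dorsal the difference was -0.50 (9.85 against 10.35, bead SE 0.05). The dimmer probe (ILMN_3007428) gave 0.99, -0.42 and 0.78 in nasal, temporal and dorsal, so the probes differed in sign in temporal and dorsal. The fitted difference of the brighter probe was 0.49 (SE 0.50, adjusted p = 0.897 in limma), and it was -0.22 without either nasal array. Where these probes lie relative to the deleted part of the gene is not known here, so the values neither bear out nor contradict the deletion, and arrays are called by their labels throughout. As the arrays of a genotype share embryos by the design text, p-values for genotype over regions are too small.

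**Figure D1:**
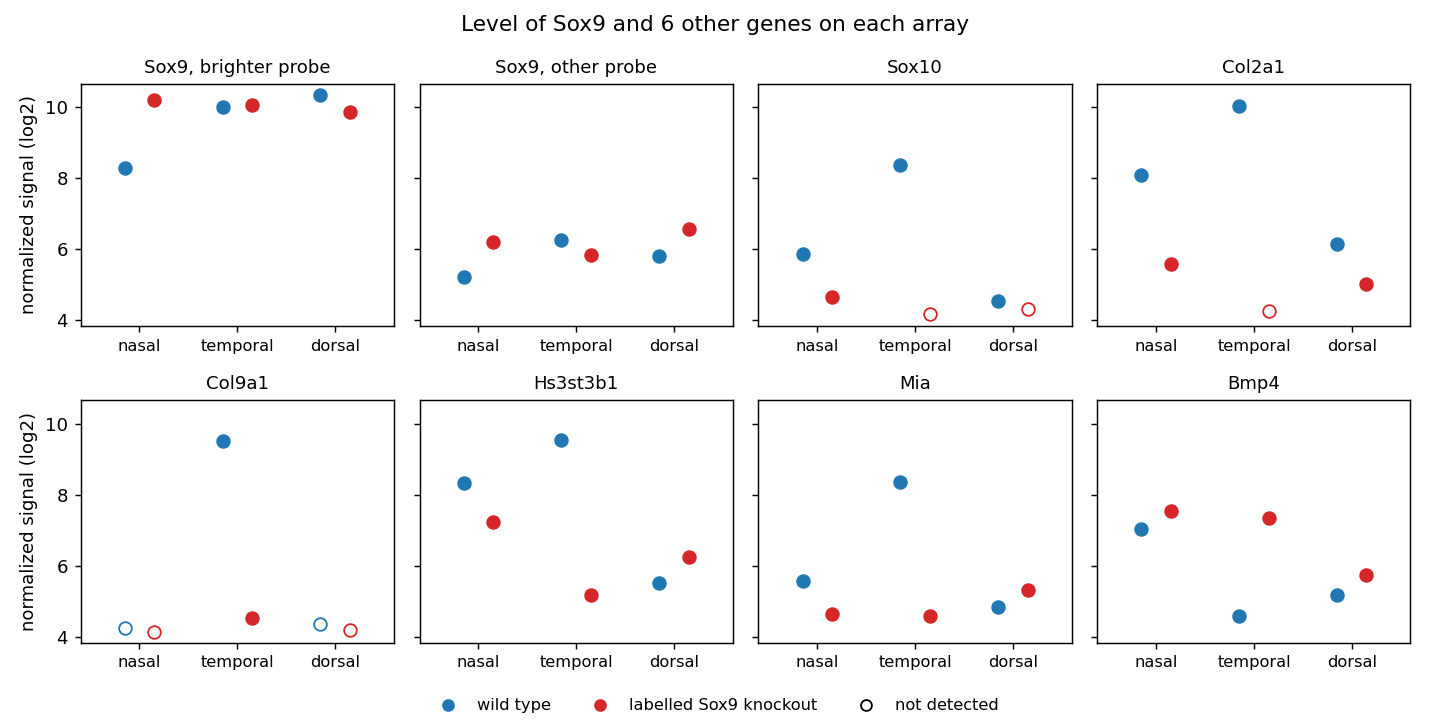
Normalized log2 signal (vertical axis) on each of the 6 arrays, by region (horizontal axis), for 2 Sox9 probes and 6 other genes, with red for arrays labelled Sox9 knockout, blue for wild type and open symbols for probes not detected. The brighter Sox9 probe stood at 8.29 on the wild-type nasal array and between 9.85 and 10.35 on the other 5, while Sox10, among genes chosen after their values were seen, stood at 8.36 on the wild-type temporal array and at 5.87 or below elsewhere.

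The comparison of arrays labelled knockout with wild type asks which genes of the conjunctival epithelium depend on Sox9. Lower on the arrays labelled knockout, with the same sign in all 3 regions, were Klf7, a Krüppel-like transcription factor (log2 difference -2.12, SE 0.24; -2.14, -2.20 and -2.03 in nasal, temporal and dorsal), and H2-T23, a non-classical class I histocompatibility gene (-1.89, SE 0.25). Ptx3, a secreted pentraxin, was detected on all 3 wild-type arrays and on 0 of the 3 labelled knockout, at least 3.36-fold lower. Sys1 showed the same detection and was at least 2.39-fold lower. Cldn11, which encodes a claudin of tight junctions, was lower by log2 values of -3.40, -1.33 and -3.22 in the 3 regions (fit -2.65, SE 0.46). Noxo1, an organizer of NADPH oxidase, was detected on 1 array labelled knockout and all 3 wild-type arrays (-2.92, SE 0.51). Jph1 (-2.06), likewise detected on 1 array labelled knockout, Rtl8b (-1.67), Arsi (-1.56), Tbcel (-1.51), Nfix (-1.36) and Limk1 (-1.30) completed the lower set.

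Higher on the arrays labelled knockout were Acbd4 (2.11, SE 0.34), Clec4b1 (1.95, SE 0.41), Tmem79 (1.92, SE 0.26) and Dsc3, a desmosomal cadherin of stratified epithelia (1.81, SE 0.37). Esrp2, a splicing regulator of epithelial cells, was 1.24, 1.38 and 1.31 higher in nasal, temporal and dorsal (fit 1.31, SE 0.24). The remaining genes of this direction were Spryd3 (1.59), Rcsd1 (1.42), Khdrbs3 (1.40), Cdk20 (1.32), Pgam2 (1.31), Bahd1 (1.27) and Stambp (1.26). None of these 24 genes passed, each with an adjusted p of 0.814 in limma, and 0 of 11147 genes did. At an unadjusted p under 0.05 limma counted 658 genes, 306 higher and 352 lower, against 557 expected by chance. The same sign in all 3 regions was seen in 3053 genes (27.4%, 25% by chance), and 277 of these differed by at least 1 log2 unit, 124 higher and 153 lower. The median 95% interval reached 0.71 log2 units to either side, and p-values are too small as, by the design text, the regions share embryos. Simulated changes of 2 log2 units were called for 49 of 50 genes where 50 changed at each of 4 sizes. That rate need not hold where fewer genes change. It can also be too high, since the simulated variances were more alike than the real ones.

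Of the 28 gene lists, FGF and ERK response genes fell as a list on the arrays labelled knockout, with 17 of 22 members lower (camera in limma, adjusted p = 0.0327). This call was lost at an adjusted p = 0.544 with an estimated correlation. That alternative also missed a simulated list of 35 genes shifted by 1 log2 unit (adjusted p = 0.107 in limma's camera). Calls lost with it, here and below, therefore decide little. Its members Spry2 and Il17rd, feedback inhibitors of FGF signalling, had log2 differences of -0.89 (SE 0.24) and -1.03 (SE 0.33), whereas Fgfbp3, which binds FGFs, had 0.91 (SE 0.31) and -0.12 with the mean of its probes. The p53 response list rose, with 14 of 17 members higher (adjusted p = 0.0327 in limma's camera, adjusted p = 0.548 with an estimated correlation), among them the DNA polymerase gene Polk at 1.02, Gtse1 at 0.95 and Ccng1 at 0.79. Gtse1 is known as a cell cycle protein that restrains p53. Notch pathway genes rose with 10 of 11 members higher (adjusted p = 0.0445 in limma's camera, adjusted p = 0.544 with an estimated correlation), led by the receptor gene Notch1 at 1.12 (SE 0.32), with the target gene Hes1 at 0.34. Macrophage markers rose (adjusted p = 0.0445 in limma's camera, adjusted p = 0.544 with an estimated correlation). Of 17 on the array 8 were tested, and 8 of 8 were higher over the regions together. By region 6, 6 and 5 of the 8 were higher in nasal, temporal and dorsal. Mrc1 was not detected on any wild-type array, so its fitted 1.20 rests on values below detection there. Lyz2 had 0.93 and the receptor gene Csf1r 0.45. On the knockout nasal array Mrc1 and Lyz2 read 6.63 and 6.57, against at most 5.17 and 5.15 on the other arrays. Median differences over members were -0.34 for the FGF list, 0.34 for p53, 0.34 for Notch and 0.40 for macrophages.

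Each of these 4 calls was lost without the temporal or without the dorsal comparison. All 4 stayed in limma's camera without the knockout nasal array. Their adjusted p was then 0.0368 for FGF, Notch and macrophages and 0.00015 for p53. Without the knockout temporal or the wild-type temporal array the FGF, Notch, p53 and macrophage lists each had an adjusted p of 0.14 in limma's camera. Without the knockout dorsal or the wild-type dorsal array the values were 0.135 for FGF, 0.231 for Notch, 0.308 for p53 and 0.135 for macrophages. Without region in the model the FGF and Notch lists had 0.0791 and the macrophage list 0.0838. Over all alternatives adjusted p ranged from 0.00126 to 0.544 for FGF, from 0.0219 to 0.544 for Notch, from 0.00015 to 0.548 for p53 and from 0.0147 to 0.544 for macrophages. With fry 0 of 28 lists passed, the smallest adjusted p being 0.255. The macrophage call also missed the threshold without background correction (0.0732), with offset 50 (0.0669), with median scaling (0.166) and without a detection filter (0.16), and Notch missed it without that filter (0.0616). As a genotype's arrays share embryos by the design text, these p-values are too small.

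Genes of glycosaminoglycan synthesis did not pass as lists in limma's camera. Heparan sulfate synthesis had 16 of 23 members lower (adjusted p = 0.543), heparan sulfate core proteins 7 of 12 lower (0.545), and chondroitin sulfate and hyaluronan synthesis 11 of 13 lower (0.0505). The syndecans Sdc2, Sdc3 and Sdc4 had log2 differences of -1.03, -1.33 and -0.71 and, named after their values were seen, Sdc1 had 0.22 and the core protein gene Col18a1 0.81. The hyaluronan synthase Has2 had -0.88, and the sulfatase Sulf2 0.74. Cartilage genes had 7 of 11 members lower (0.138), with Col2a1, the main collagen of cartilage, at -3.15 (SE 0.86). The basement membrane list had 15 of 20 lower (0.138, Col4a2 -1.02), and the ocular gland list 9 of 16 lower (0.187), with the epithelial factor Ehf at -1.86, Sox10 at -1.87 (SE 0.75) and Mia at -1.41. Wnt genes had 16 of 24 higher (0.138), with Myc at -1.21 and Wnt7b at 1.06, and BMP genes 6 of 11 higher (0.545, Bmp4 1.26). Hedgehog genes had 5 of 9 higher (0.759), keratins and adhesion genes 19 of 28 higher (0.0633), cornea and conjunctiva genes 7 of 12 lower (0.794), epidermal genes 8 of 12 higher (0.138) and placode genes 5 of 9 lower (0.759). Cell cycle genes had 21 of 35 lower (0.24), immediate early genes 8 of 15 higher (0.192, Dusp1 1.13) and hypoxia genes 12 of 20 higher (0.0505, the glucose transporter gene Slc2a3 1.09). Adjusted over the list alone, limma passed 2 genes, the Hedgehog receptor gene Ptch1 (1.18, SE 0.26) and Esrp2 in the keratin list, against 0 over all genes. These p-values too are too small as, by the design text, regions share embryos.

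Markers of other cell types than macrophages did not pass in limma's camera. Periocular mesenchyme had 14 of 22 members lower (adjusted p = 0.545), lens 6 of 8 higher (0.67), neural retina 3 of 5 higher (0.697), pigment cells 4 of 6 higher (0.759), skeletal muscle 4 of 8 higher (0.794), erythroid cells 5 of 8 lower (0.889), endothelium 2 of 3 higher (0.545) and nerve and Schwann cells 3 of 5 lower (0.67). The lens factor Prox1 was at 1.56 (SE 0.39). P-values over regions are too small as, by the design text, these share embryos.

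In temporal epithelium 1766 of 10460 genes (16.9%) differed at least 2-fold between the arrays, 897 higher and 869 lower on the array labelled knockout. Lower genes detected on both arrays included Col9a1, a cartilage collagen (31.5-fold, log2 difference -4.98, bead SE 0.15), Trub2 (21.2-fold, -4.41), Hs3st3b1, which adds 3-O-sulfate to heparan sulfate (20.5-fold, -4.36), and the semaphorin Sema3b (16.3-fold, -4.02), and higher ones Fbxo2 (12.6-fold, 3.65), Trim68 (12.5-fold, 3.64), Il1rapl2 (11.9-fold, 3.57) and the basal keratin Krt17 (10.7-fold, 3.43). Within the fixed lists, and chosen after their values were seen, Col2a1 was at least 45.7-fold lower, Sox10, a transcription factor of gland buds and of neural crest glia, at least 14.3-fold, Hs3st3a1 at least 5.82-fold, Col9a2 at least 5.4-fold, Shisa2 at least 4.44-fold and Col9a3 at least 4.08-fold. Mia was 13.7-fold and the syndecan Sdc3 6.8-fold lower. Col9a1 stood at the lowest detected level of the knockout array (4.53), and of its other probes 1 read 4.29 against 5.15 and 2 were not detected on any array. Higher members of lists included Lum (2.84), Bmp4 (2.73, 6.64-fold), Prox1 (2.59) and Cdkn1a (2.04), with Lef1 at least 5.74-fold higher.

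The lists that stood apart in temporal, by the percentile of their median among 10000 random lists of the same size and brightness, included heparan sulfate synthesis (median -0.64, percentile 0.1), FGF and ERK response (-0.50, percentile 0.1) and the ocular gland list (-0.53, percentile 0.5). At the other end were Wnt (0.51, percentile 99.9), immediate early genes (0.58, percentile 99.9), p53 response (0.58, percentile 99.8), keratins and adhesion (0.34, percentile 99.8) and epidermal genes (0.41, percentile 98). Markers of Schwann cells and nerve had a median of -2.20 over 5 members (percentile 0), with the receptor gene Erbb3, named after its values were seen, 5.42-fold and the lipid-binding protein gene Fabp7 4.88-fold lower and Ngfr at least 4.54-fold lower. The percentiles describe these 2 arrays and test no effect of genotype.

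In nasal epithelium 2169 of 10320 genes (21%) differed at least 2-fold, 1087 higher and 1082 lower. Of genes detected on both arrays, the peroxisomal gene Pex6 (13.5-fold, log2 difference 3.75), Mob3b (10.5-fold, 3.39), the water channel gene Aqp1 (10.4-fold, 3.38) and P4ha1, a collagen prolyl hydroxylase (10.2-fold, 3.35), were higher on the array labelled knockout. Zcchc24 (13.8-fold, -3.79), Ttc19 (10.6-fold, -3.41), Cldn11 (10.6-fold, -3.40) and the tumour necrosis factor receptor gene Tnfrsf1a (10.2-fold, -3.35) were lower. Of list members chosen after their values were seen, Ehf was at least 7.08-fold and Col2a1 5.66-fold lower, Sox10 2.32-fold lower, Mrc1 at least 4.4-fold higher and the heparan sulfate sulfotransferase gene Ndst2 6.43-fold higher. The p53 list had a median of -0.10 in nasal, with 11 of 17 members lower (percentile 40.1). Hypoxia and glycolysis genes had a median of 0.48 (percentile 100), macrophage markers 0.74 (percentile 99.4), endothelium 0.68 over 3 genes (percentile 97.8), FGF and ERK response -0.33 (percentile 1.5) and placode genes -0.51 (percentile 2.6).

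In dorsal epithelium 685 of 10553 genes (6.5%) differed at least 2-fold, 332 higher and 353 lower. Of genes detected on both arrays, Laptm5, a lysosomal protein gene of blood cells and a member of the macrophage list, was 6.3-fold higher (log2 difference 2.66). Mapk11 (5.31-fold, 2.41), Ankrd37 (4.84-fold, 2.27) and Dap (4.54-fold, 2.18) were also higher. Cldn11 (9.29-fold, -3.22), Tuft1 (6.41-fold, -2.68), Prkg1 (5.36-fold, -2.42) and Akap8l (5.19-fold, -2.38) were lower. The p53 list had a median of 0.54 (percentile 100), Notch 0.41 (percentile 99.2), macrophages 0.44 (percentile 98.9), hypoxia 0.21 (percentile 98.2), erythroid genes -0.53 (percentile 0.7), basement membrane genes -0.25 (percentile 1) and cornea and conjunctiva genes -0.24 (percentile 2.6).

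**Figure D2:**
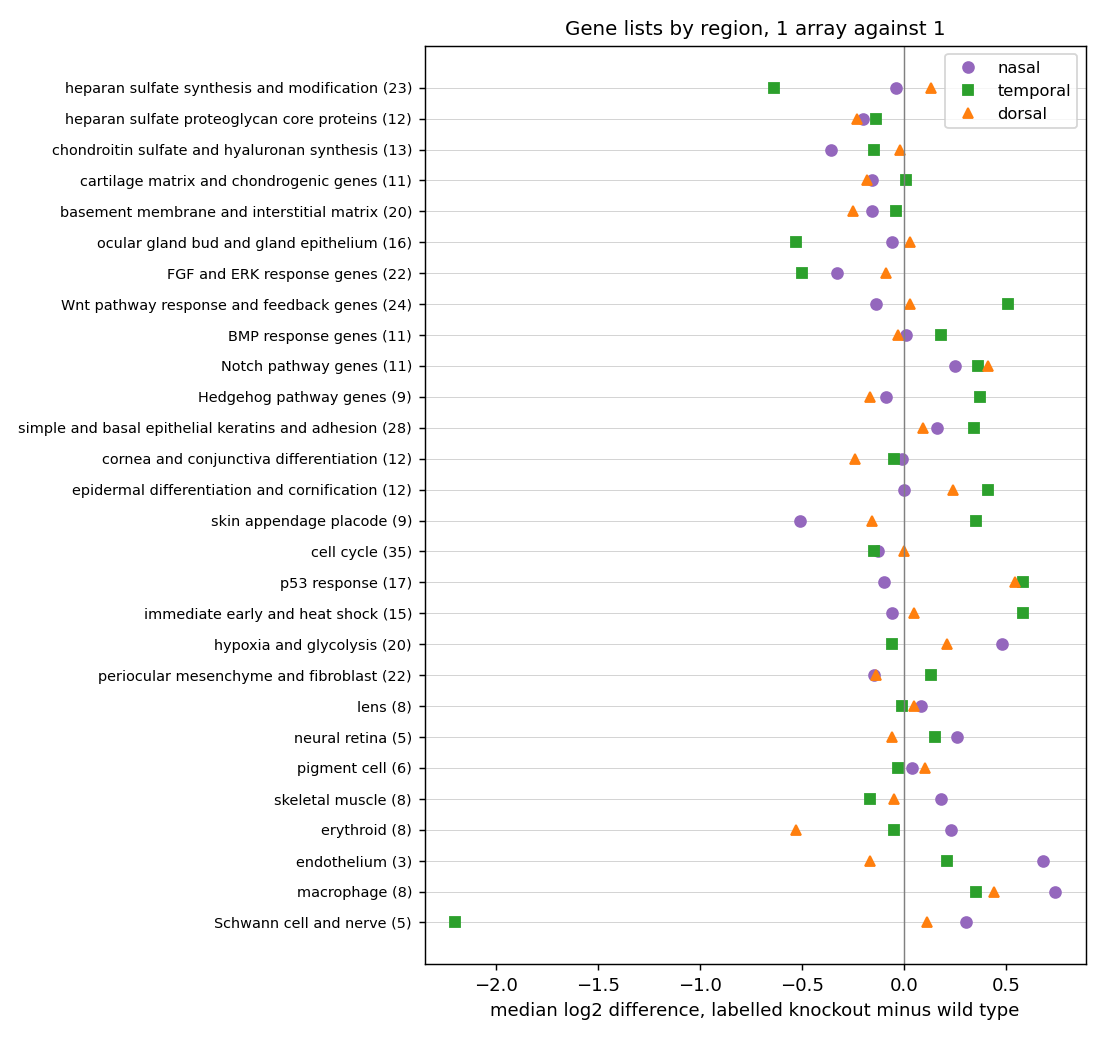
Median log2 difference of each of 28 gene lists between the array labelled knockout and the wild-type array (horizontal axis), with a purple circle for nasal, a green square for temporal and an orange triangle for dorsal, and the number of genes in brackets beside each list name. The nerve list lay at -2.20 in temporal and at 0.30 and 0.11 in nasal and dorsal.

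Across genes the knockout differences of 1 region were nearly unrelated to those of another, with Pearson correlations of 0.075 for nasal and temporal, 0.039 for nasal and dorsal and 0.052 for temporal and dorsal over 11147 genes, which are not independent replicates. Measurement limits such values, as 2 probes of a gene correlated at only 0.27, 0.32 and 0.25 within nasal, temporal and dorsal (2520 genes). Low correlations between regions therefore do not show that the regions respond differently. In nasal and temporal 122 genes were at least 2-fold higher in both (87.5 by independent lists), 168 lower in both (84.4) and 215 opposite (171.8). Nasal and dorsal shared 56 higher (32.4) and 74 lower genes (34.3), and temporal and dorsal 61 higher (26.7) and 61 lower (27.5). With median scaling the share of higher genes moved from 50.1%, 50.8% and 48.5% to 65%, 65.1% and 77.8% in nasal, temporal and dorsal, as the median of all genes moved to 0.17, 0.10 and 0.21 log2 units. Without background correction 536, 387 and 57 genes differed at least 2-fold.

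**Figure D3:**
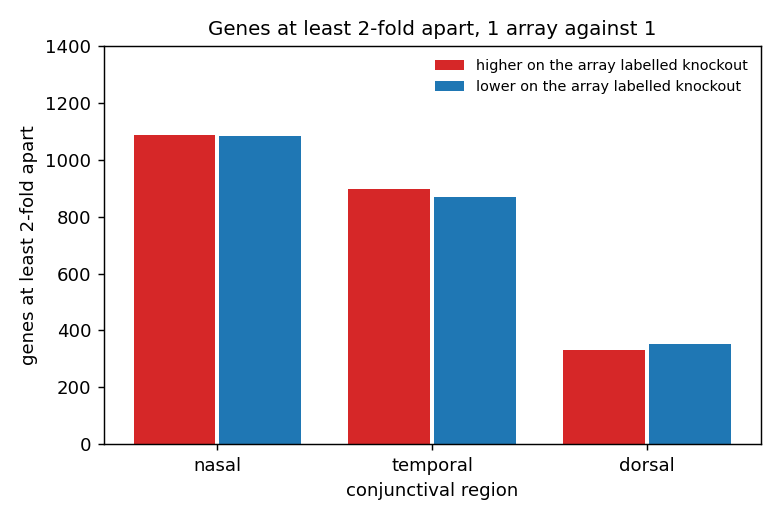
Number of genes at least 2-fold apart (vertical axis) between the array labelled knockout and the wild-type array in each conjunctival region (horizontal axis), with red bars for genes higher and blue bars for genes lower on the array labelled knockout. The bars stood at 1087 and 1082 in nasal, 897 and 869 in temporal and 332 and 353 in dorsal.

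Whether the genotype difference in dorsal epithelium departed from that in the gland-forming regions was tested as an interaction. Bbc3, a p53 target that promotes apoptosis, had a dorsal difference of 2.12 against at least 2.49-fold lower in nasal and 2.46-fold lower in temporal (interaction 3.52, SE 0.58). Lhfpl2 (3.28), Nr2c2ap (3.10), Jade3 (2.99), Zbtb41 (2.83) and Klhl2 (2.83) had the same direction. Akap8l (-3.68), the dynein gene Dync2h1 (-3.55), Ypel3 (-3.07), Uxs1, which makes the UDP-xylose used for proteoglycans (-2.90), Coq6 (-2.76) and Primpol (-2.69) had the opposite. In limma 0 of 11147 genes passed (adjusted p = 1 for each of these 12), with 232 at an unadjusted p under 0.05 and 557 expected by chance. With 1 residual degree of freedom, simulated differences of 2 log2 units were called for 2 of 50 genes and those of 4 units for 37 of 50. These rates can likewise be too high. The p-values measure only the spread between arrays.

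Gland-forming nasal and temporal epithelium was compared with dorsal over both genotypes. Hey1, a target of Notch signalling, was higher in nasal and temporal by 1.62 (SE 0.28), along with Dnaaf2 (1.32), Nat2 (1.30), the phospholipase gene Plcb4 (1.24) and Capn6 (1.15), and Adamts9, a secreted protease gene not detected on either dorsal array, was at least 2.18-fold higher. Dbndd2 (-2.52), Vat1l (-2.40), Rnf135 (-1.90) and the semaphorin Sema3e (-1.67) were lower. Mapk15 and Zfp526, not detected on any nasal or temporal array, were at least 2.89-fold and 2.57-fold lower. In wild type alone, without a test, Hey1 read 7.12 in nasal, 7.23 in temporal and 5.84 in dorsal, and Vat1l read 4.28, 4.65 and 7.13. Limma passed 0 of 11147 genes (adjusted p = 0.999 for these 12), with 427 at an unadjusted p under 0.05, 146 without the knockout dorsal array and 889 without the wild-type nasal array. These p-values measure only the spread between arrays. Embryos common to all arrays of a genotype are taken up by the genotype term, but embryos that differ between its arrays are not. Whether they differ is open. The Y-linked gene Eif2s3y read 4.90 on the wild-type temporal array and 6.65 and 6.75 on the wild-type nasal and dorsal arrays, while the Y-linked gene Uty was detected on all 3 (4.68, 4.83 and 5.08).

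Cell cycle genes fell as a list in nasal and temporal relative to dorsal epithelium, with 28 of 35 members lower (camera in limma, adjusted p = 0.00401), though with an adjusted p = 0.721 with an estimated correlation. Foxm1, a transcription factor of mitotic genes, was at -0.96, the thymidine kinase gene Tk1 at -0.84, Top2a at -0.66 and Aurkb at -0.58. The dorsal arrays also had the most detected probes (44.9% and 45.6%, against 39.8% to 44.1% on the others). Whether this bears on the list was not tested. Without the knockout dorsal array the list had an adjusted p of 0.0929 and without the wild-type dorsal array 0.0637 in limma's camera, and over its alternatives it ranged from 5.07e-05 to 0.721. The mesenchyme list had 18 of 22 members lower (0.0522) and the FGF list 15 of 22 higher (0.147). With fry 0 lists passed (smallest adjusted p = 0.401). The heparan sulfate synthesis list had a mean of 0.01 and a median of -0.27, and the Notch list 0.01 and -0.02, both with a lower direction in camera, while chondroitin sulfate synthesis had 0.05 and -0.01 with a higher direction. Adjusted over the list alone limma passed 3 genes, Hey1, the cartilage link protein gene Hapln1 (-1.62) and the lens water channel gene Mip (-1.42), named after their values were seen, against 0 over all genes. These p-values too measure only the spread between arrays.

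Between the gland-forming regions, Tgfb2, which encodes a growth factor of the TGF-beta family, was higher in nasal than temporal epithelium by 3.25 (SE 0.41). The proteoglycan gene Dcn (2.39), Ntn3 (2.38), the cell cycle inhibitor gene Cdkn2b (2.37), Runx1t1 (2.28) and Sepsecs (2.19) followed. Il6ra, the interleukin 6 receptor gene, was not detected on either nasal array and was at least 4.75-fold lower there, and Tcaf2 (-2.22), the zinc transporter gene Slc30a6 (-2.04), Mfsd11 (-1.90), Fxyd3 (-1.83) and Plac8 (-1.77) were also lower, but Mfsd11 had 0.50 with its probe detected on all 6 arrays. Limma passed 0 of 11147 genes (adjusted p = 0.69 for these 12) and counted 789 at an unadjusted p under 0.05, 433 without the knockout temporal array, 526 without either dorsal array and 1529 without the wild-type nasal array. Each region had 2 arrays, and the p-values measure only the spread between arrays. Embryos that differ between the arrays of a genotype would enter this contrast too.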

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

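The tests of cartilage cells, nerve glia, a response shared with nasal epithelium, exchanged arrays, probe position and bead noise were chosen after the results they bear on were seen, while those of a generally deviating array, of lost transcripts and of other splits of the arrays were chosen before.

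Genes that moved in opposite directions in 2 regions drew attention first. At least 2-fold apart with opposite signs were 215 genes in nasal and temporal, 84 in nasal and dorsal (66.6 by independent lists) and 74 in temporal and dorsal (54.3), and the difference was not tested in these counts. Trim68 differed by 3.64 in temporal and -1.21 in nasal, and the difference was not tested. Laptm5 differed by 2.66 in dorsal and was at least 3.14-fold lower in nasal. Ankrd37 differed by 2.27 in dorsal and -1.76 in temporal, Tuft1 by -2.68 in dorsal and 1.04 in temporal, and Akap8l by -2.38 in dorsal and 1.71 in nasal. For Laptm5, Ankrd37 and Tuft1 the difference was not tested between those 2 regions, and the interaction of Akap8l did not pass in limma (adjusted p = 1). Among probes without a gene name here, 4032 were detected on at least 2 arrays, and limma passed 0 of them, with 203 at an unadjusted p under 0.05. Groups of 3 arrays were not searched for single deviating arrays.

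Sox9 was 1.92 log2 units higher on the array labelled knockout in nasal and -0.50 different in dorsal, and the difference was not tested between these regions, while the interaction of dorsal against both gland-forming regions was -1.48 for Sox9 (adjusted p = 1 in limma). If both nasal arrays had been exchanged between genotypes, genes far lower in temporal could be expected to be higher on the array labelled knockout nasal. Their median there was -0.44, which argues against an exchange only if nasal and temporal epithelium respond alike, and that is open. Sox9 probes outside the deleted part could explain why the brighter probe differed by only 0.05 in temporal, and without the positions of probe and deletion this cannot be told apart from RNA of cells that kept the gene. A difference between regions in how Sox9 is regulated stays open and was not tested.

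Many genes, among them Col2a1, Col9a1, Trub2, Hs3st3b1, Rhoj, Sox10 and Mia, were far lower on the knockout temporal than on the wild-type temporal array. Cartilage cells in the wild-type capture stay open. The 11 detected cartilage genes had a median temporal difference of 0.01 (SD 2.36). Col2a1, Col9a1, Col9a2 and Col9a3 (4 genes) were at least 2-fold lower and 1, Sox5, as far higher. Acan (4.46), Fmod, Hapln1 and Matn4 were not detected on the wild-type temporal array, so the median rests partly on values near the floor and cannot decide. Col2a1 stood at 10.04 on that array, while Matn1 (4.31) and Comp, outside the 11, were not detected on it. Nerve glia may account for Sox10, as 5 nerve markers had a median of -2.20, although Foxd3 was higher by 0.65. Erbb3 (7.76 on the wild-type temporal array) also read 8.35 on the knockout nasal array beside Sox10 at 4.66, and Mbp (5.70) read up to 6.13 elsewhere. No S100b, Cdh19 or Gap43 was detected on the wild-type temporal array, while 1 Nefm probe was detected on that array alone (4.86) and the other Nefm probes on none. A knockout response shared with nasal epithelium is open: 97 genes at least 2 log2 units lower in temporal had a nasal median of -0.44 (95% bootstrap interval -0.70 to -0.18, brightness-matched sets -0.20 to 0.17), short of the -0.5 set for it, and -0.18 in dorsal (-0.11 to 0.11), while 113 genes as far higher in temporal had 0.01 in nasal (-0.14 to 0.09). The wild-type temporal array had 10 genes at least 2 log2 units above every other array, against 23, 17, 6, 0 and 0 on the others, but 0 as far below, and its median correlation across genes with the others was 0.93 (0.882 to 0.934 for the other 5), so a general deviation is not shown, while Eif2s3y, a Y-linked gene at 4.90 there and 6.65 to 7.60 elsewhere, leaves a different make-up of embryos open and untested.

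More genes were 2-fold apart in nasal and temporal than in dorsal epithelium. In nasal, noise between beads is argued against as the whole source among genes with 2 probes detected on all 6 arrays. Dimmer genes, which the counts of 2-fold differences include, were not covered by this test. A second probe of the gene had the same sign for 68.4% of 478 nasal genes (327 genes, exact 95% interval 64% to 72.6%), above the 56.2% that the excess over dorsal would give as noise. The share was 71.8% of 372 genes in temporal, not set against a noise value, and 71.5% of 137 in dorsal. Differences of 2 probes of a gene had Pearson correlations of only 0.27, 0.32 and 0.25 in nasal, temporal and dorsal (2520 genes). A fold from 1 probe is thus less certain than its bead SE implies. Random loss of transcripts on the knockout nasal and temporal arrays stays open, as 11 housekeeping genes went undetected on 1 of these arrays alone against 11.1 expected from brightness, a ratio of 0.99 (95% interval 0.5 to 1.78) that does not set them apart from the other 4 arrays (2, 2, 2 and 0 against 1.18, 1.79, 2.54 and 0.79). Of genes detected on the other 5 arrays, 6.24% were undetected on the knockout nasal and 4.13% on the knockout temporal array, against 0.78% to 2.44% on the other 4. A greater response to the loss of Sox9 in gland-forming regions is the biological explanation the design offers, and it cannot be separated from such losses with 1 array per genotype and region.

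The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 of 10 splits gave 0 genes past the threshold in limma, the highest other count being 0. The real split gave 658 genes at an unadjusted p under 0.05, and 5 of 10 splits gave as many, the highest other count being 1358. For gene lists the real split gave 4, and 3 of 10 gave as many, the highest other count being 10. Splits that kept both arrays of at least 1 region together gave 1358, 865 or 118 genes with 0, 10 or 2 lists. With region in the model these splits compare the arrays of 1 region alone, and each such fit recurs, so they are no like comparison. The others that parted every region gave 510, 463 and 439 genes with 0, 1 and 1 lists. Among splits that parted every region the real one was highest, but these are too few to test it.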

How the results depend on the processing

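The list test on nasal against temporal and the other Sox9 probe were added after the data were seen. In limma 0 genes passed in each comparison under every alternative run. Counts at an unadjusted p under 0.05 ranged from 455 to 1106 for the knockout over 21 settings, 146 to 898 for nasal and temporal against dorsal, 433 to 1529 for nasal against temporal and 150 to 837 for the interaction. The smallest adjusted p lay between 0.435 and 0.922, 0.483 and 1, 0.147 and 0.999, and 0.529 and 1, and those for the knockout are too small as, by the design text, regions share embryos. Without an array the interaction had no residual degrees of freedom and was not tested. Where a genotype lost an array of a region, its partner no longer informed the knockout contrast.

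For the knockout (4 lists) the number of passing lists was 7 with median scaling, 1 without covariates, 8 with a variance trend, 0 with an estimated correlation and 0 with fry. Leaving out 1 array gave 0 to 8, with 8 without either nasal array, 1 without either temporal array and 0 without either dorsal array, and leaving out the nasal, temporal or dorsal pair gave 8, 1 and 0. For nasal and temporal against dorsal (1 list) it was 2 with median scaling, 2 with the authors' values, 2 without a detection filter, 3 over genes detected on all 6 arrays, 2 with the mean of probes, 2 without covariates, 2 with array weights, and 0 with an estimated correlation or fry (0). Leaving out 1 array gave 0 to 3: 3 without the knockout temporal or wild-type nasal array, 2 without the knockout dorsal and 0 without the wild-type dorsal. For nasal against temporal (1 list) it was 2 without a filter, 0 over genes detected on all 6 arrays, 3 with the mean of probes, 2 with a variance trend, and 0 with an estimated correlation or fry (0). Leaving out 1 array gave 0 to 7: 7 without the knockout temporal and 0 without the wild-type temporal or wild-type nasal array. The cause was not tested.

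Sox9 had 0.49, from -0.22 to 0.99 when 1 array was left out, with -0.22 without either nasal array or the nasal pair, and 0.45 with its other probe. Fgfbp3 turned to -0.12 with the mean of its probes, and Mfsd11 to 0.50 with the probe detected on all 6 arrays. Left-out arrays moved Egfl7 between -0.11 and 0.77 and Ramp2 between -0.21 and 0.02, and the nasal pair gave -0.11 for Egfl7 and the dorsal pair 0.02 for Ramp2. The cause was not tested. Genes at least 2-fold apart in nasal, temporal and dorsal numbered 536, 387 and 57 without background correction, and 319, 210 and 25 were at least 4-fold apart. Replicate numbers follow the order of the samples and pair no arrays, while region, which pairs 1 array of each genotype, was in the knockout model except in the setting without covariates. Signal over background limits dim genes, since 39.8% to 45.6% of probes were detected on an array.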

Other observations

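The list test on nasal against temporal epithelium and the genes Sfrp1, Lef1 and Sp5 were chosen after the data were seen. Wnt response and feedback genes rose as a list in nasal relative to temporal epithelium, with 20 of 24 members higher (camera in limma, adjusted p = 6.94e-05), though with an adjusted p = 0.859 with an estimated correlation. Axin2, the general feedback gene of Wnt signalling, was not detected on either temporal array and was at least 3.61-fold higher in nasal. Nkd1 (2.13), the secreted inhibitor gene Wif1 (1.23) and Znrf3 (1.18), a ligase that removes Wnt receptors, had the same direction, while the secreted inhibitor gene Sfrp1 had -1.12. Adjusted over the list alone, limma passed the Wnt genes Nkd1 and Axin2 and the mesenchyme gene Dcn, 3 in all, against 0 over all genes. The list had an adjusted p of 0.334 without the wild-type temporal array, 0.0769 without the wild-type nasal array and 0.0581 over genes detected on all 6 arrays, and ranged from 2.82e-07 to 0.859 over its alternatives. With fry 0 of 28 lists passed (smallest adjusted p = 0.341), and p-values measure only the spread between arrays.

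In wild type, Lef1, a transcription factor of Wnt signalling, read 7.86 in nasal and 4.31 in temporal epithelium, where it was not detected, and Sp5, a Wnt target, read 7.31 and 4.30. On the arrays labelled knockout Lef1 read 6.69 in nasal and 6.99 in temporal, and Sp5 read 6.71 and 5.91. The nasal against temporal difference of these genes was not tested within a genotype.

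Xist read between 8.27 and 9.22 on all 6 arrays, and the Y-linked gene Kdm5d read 4.34 on the wild-type temporal array, where it was not detected, and between 4.66 and 5.88 on the other 5. By its brightest probe Uty was detected on the wild-type temporal array (4.68) but not on the knockout nasal or knockout temporal array. Another Uty probe was detected on the knockout nasal array (4.65) and not on the wild-type temporal array (4.19), so the probes disagreed.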
